A study of Mus musculus with 2 samples.

How the data were processed

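RNA was measured in ureters dissected from mouse embryos at E14.5, in which the gene Rbpj was removed with a Cre recombinase expressed from the Tbx18 locus (Rbpj-cKO), and in ureters of control embryos carrying a floxed Rbpj allele. The labels list 2 samples, each a 2-colour Agilent array on which Rbpj-cKO and control RNA were hybridised together. Per the labels' protocols, 150 ng of total RNA was the input for each labelling. On replicate 1 the RNA came from male embryos and Rbpj-cKO carried AlexaFluor647 (red). On replicate 2 the RNA came from female embryos and Rbpj-cKO carried AlexaFluor555 (green). Dye orientation and sex therefore change together between the arrays. The labels do not say how many embryos gave the RNA of a channel.

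Each spot's mean intensity and its local background median intensity, red and green, were deposited on a linear scale with no normalization, per the file headers. The deposited processed intensity of each channel is the scanner software's own value after background subtraction, detrending and dye normalization, per the file headers. The log10 ratio deposited per spot is red over green of those processed intensities, per the file headers. Further columns deposited per spot are flags of the scanner software, coded as other values of 0 or 1, for signals well above background, saturation and outliers. The software was Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. Probe coordinates are on the mouse build mm9, per the file headers. Both arrays were sub-arrays of 1 slide read in 1 scan, so slide and scan did not separate them.

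The authors also deposited a series table with 1 value per probe and array. No value lies between -1 and 1, 11196 values of replicate 1 and 11570 of replicate 2 are exactly 1, and both medians are 1. Its log2 size with its sign ran with the processed log2 ratio of Rbpj-cKO over control (r = 0.781 on replicate 1 and 0.849 on replicate 2 across probes, median absolute difference 0.017 and 0.021). The table was therefore read as a signed linear fold change of Rbpj-cKO over control, already turned for the dye orientation by the authors. The method behind these ratios is not given in the sources used here, and they served only as an alternative.

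Background was corrected with normexp (offset 50) on the mean and background median signals of all spots, and the log2 ratios were normalized within each array by loess with weight 0 for the 17263 control spots, in limma 3.58.1 under R 4.3.3. The design has 39429 probes with 4 spots each. Spots with an outlier flag (3.6% on replicate 1 and 3.9% on replicate 2) were left out, no spot was saturated, and the remaining spots of a probe were averaged. Red over green was multiplied by -1 on replicate 2, so that every ratio is Rbpj-cKO over control. A dye effect common to both arrays cancels in the mean of the ratios.

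A total of 28328 probes were named through their RefSeq accession in a RefSeq gene table of mouse, 3400 carried a symbol found in that table, and 7701 kept the name in the file. A probe was kept when at least 2 of its 4 spots were well above background in at least 1 channel on each array, which left 26980 probes. The brightest probe stood for each gene, which gave 20495 genes, 5113 of them with more than 1 probe past the filter. The genome build of the RefSeq table is another than that of the array's coordinates, so the table was used for names only.

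Each gene's mean log2 ratio was tested against 0 with lmFit and eBayes of limma (two-sided, Benjamini-Hochberg adjustment over all genes), with 1 residual degree of freedom and 5.57 prior degrees of freedom. As a description with no p, genes with at least a 1.5-fold difference the same way on both arrays were counted beside those with such a difference in opposite directions. A total of 13 pathway lists and 13 cell type lists were fixed before the data were examined. The 25 lists other than the sex-linked genes were tested with camera of limma (preset inter-gene correlation 0.01, Benjamini-Hochberg adjustment over the lists), and again with an estimated correlation and with fry. The preset takes genes as nearly independent of one another. Its p-values thus rest on the spread between genes and do not measure that between samples. A list's median on an array was ranked among the medians of 10000 random lists matched on mean intensity. Named genes follow a rule fixed before the data were examined. It takes the 12 genes higher and the 12 lower with the largest mean log2 ratio among those passing both the test and the 1.5-fold rule, filled up from the 1.5-fold genes where too few pass. It leaves out clone, predicted-gene and accession names, and adds 17 fixed genes and up to 4 members of each list with the smallest adjusted p. Any further gene is given as chosen after its value was seen, and some list members are not reported here.

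Channel levels given for sex-linked genes are the processed signals. The whole procedure was tested on simulated spots for the comparison of Rbpj-cKO against control, with 200 of 20495 genes changed and a spread per gene like that of the fit. Of simulated changes of 1.5-fold, 1.49% passed at adjusted p under 0.05 and 8.96% met the 1.5-fold rule. At 2-fold these shares were 82.1% and 89.6%, and at 4-fold both were 100%. Of the unchanged genes 0.00493% passed. A simulated list of 20 genes shifted by 0.4 (log2) had a camera adjusted p of 1.01e-28 with the preset correlation, 0.89 with an estimated correlation and 0.536 with fry, and 0 of 25 unshifted lists were called with the preset correlation. The simulated arrays ran opposite ways over the unchanged genes (r = -0.338), but genes were drawn independently of one another, so the lists held no correlated genes. In the real data, 0 of the 9 genes at least 2-fold the same way on both arrays passed, so the simulated shares may not carry over.

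Alternatives covered the background correction and its offset, median centring, scaling between arrays, the authors' fold changes, the filter on dim probes, the probe rule, outlier spots, the moderation of the variance, the thresholds and leaving out each array. The number of arrays limits the precision of every value.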

Results

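Gene expression was compared between Rbpj-cKO and control mouse ureters at E14.5 on 2 arrays, each holding both genotypes. Rbpj encodes the DNA-binding partner of the Notch intracellular domain, and Tbx18, whose locus drives the Cre recombinase, is expressed in the mesenchyme around the ureteric epithelium. The comparison addresses which transcripts of the ureter depend on Rbpj in that mesenchyme. Replicate 1 held male and replicate 2 female embryos, with the dyes exchanged between them. On replicate 1, 69.3% of the spots were well above background for Rbpj-cKO and 70.1% for control, and on replicate 2 these shares were 68.1% and 67.7%. The median spot SD of a probe's log2 ratio was 0.039 on replicate 1 and 0.054 on replicate 2. Ratios below are log2 of Rbpj-cKO over control, given as the mean ± SD of n = 2 arrays or as the values of replicate 1 and replicate 2 in that order.

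Rbpj itself was lower in Rbpj-cKO on both arrays. The brighter of its probes (mm9 chromosome 5, positions 54048503 to 54048562) had log2 ratios of -1.13 and -0.63, a mean of -0.88 ± 0.35 (SD, n = 2) or 1.84-fold less (limma adjusted p = 0.776). The other probe (chromosome 5, 54044777 to 54044836) had -0.48 and -0.37, a mean of -0.42 ± 0.079. Where these probes lie relative to the deleted exons is not given in the sources used here. Tbx18 (chromosome 9, 87599514 to 87599573) had 0.17 and -0.24, a mean of -0.03 ± 0.29.

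The genes with the largest ratios the same way on both arrays included catecholamine and granin genes on the higher side and the smooth muscle coactivator gene Myocd on the lower side. Of the 27 higher genes, 4 (Chgb, Chga, Dbh and Phox2a) belong to the fixed list of neural crest, glia and neuron genes. Chgb and Chga, which encode granins of secretory granules, had mean log2 ratios of 1.80 ± 1.46 and 1.53 ± 0.82. Dbh, the enzyme that makes noradrenaline from dopamine, had 1.26 ± 0.80, and Slc18a1, a vesicular monoamine transporter, 1.23 ± 0.35. Insm1, a transcription factor of neuroendocrine cells, had 1.12 ± 0.10, and Phox2a, a transcription factor of autonomic neurons, 0.95 ± 0.44. Further higher genes were Gsdmc3 at 1.61 ± 0.75, the renin gene Ren2 at 1.43 ± 0.08, Resp18 at 1.17 ± 0.037, the Notch target Hey1 at 1.08 ± 0.39, Dusp26 at 1.02 ± 0.066 and Hand2os1 at 0.96 ± 0.47. A second probe of Gsdmc3 gave a mean of 0.42. None of these genes passed the test, with limma adjusted p from 0.254 for Ren2 and Resp18 to 1 for Chgb and Dbh.

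On the lower side, Mdfi, which encodes an inhibitor of myogenic transcription factors, had -1.28 and -1.24, a mean of -1.26 ± 0.027. Myocd had -0.67 and -1.04, a mean of -0.86 ± 0.26. Car3, a carbonic anhydrase, had -1.17 ± 0.48, the paired-box gene Pax1 -1.07 ± 0.68, and Aspn, a small proteoglycan of the matrix, -1.07 ± 0.19. Pi4k2b, a lipid kinase gene, had -1.02 ± 0.06, Shisa2 -0.89 ± 0.031, C1ql3 -0.76 ± 0.14 and Nyap1 -0.75 ± 0.18. Anp32a had the lowest mean at -1.82 ± 0.75, and Colq, the collagen tail of acetylcholinesterase, had -0.82 ± 0.015. Their other probes went by -0.18 for Colq and 0.02 for Anp32a, so these ratios belong to single probes. None of these genes passed the test either, with limma adjusted p from 0.254 for Mdfi to 1 for Pax1.

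**Figure D1:**
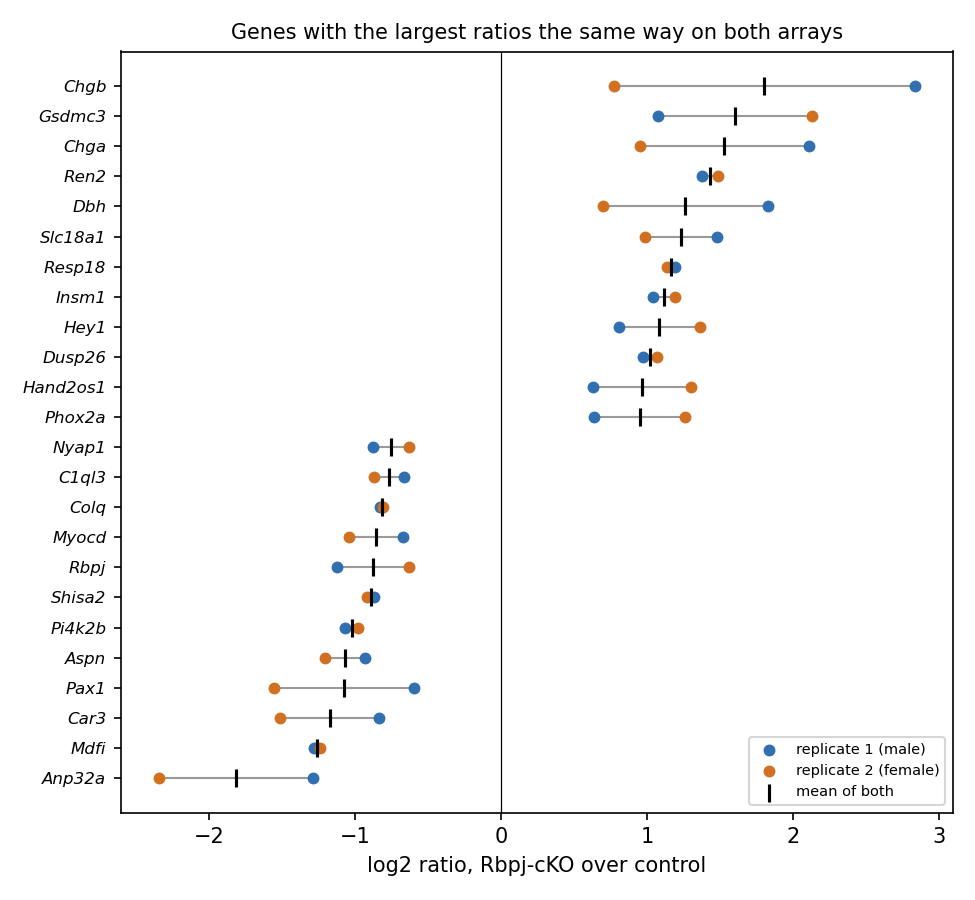
Log2 ratio of Rbpj-cKO over control (horizontal axis) for the 12 higher and 12 lower named genes with the largest mean ratios, 1 row per gene. Blue and orange points are replicate 1 (male) and replicate 2 (female), and the black bar is their mean. Chgb reaches 2.83 on replicate 1 and 0.77 on replicate 2, while Mdfi lies at -1.28 and -1.24.

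In all, 0 of 20495 genes had an adjusted p under 0.05 with limma, and the smallest adjusted p was 0.254. At an unadjusted p under 0.05 there were 372 genes, 264 higher and 108 lower. With no change and independent arrays, 1025 would be expected. The arrays ran opposite ways across genes (r = -0.352), which widens the spread that the test uses. Its p-values therefore run high, and the low counts do not show that few genes changed. With an intensity trend and robust moderation of the variance in limma, 5 genes had an adjusted p under 0.05, named here after their values were seen. They were Ren2, Mdfi and the clone-named genes 9430037G07Rik (0.90 and 0.91), D030062O11Rik (1.14 and 1.39) and Gm19410 (mean 1.14), all with an adjusted p of 0.0309. At least 1.5-fold the same way on both arrays were 40 genes, 27 higher and 13 lower, where 4.56 would be expected if the arrays were independent. Another 147 genes differed at least 1.5-fold on both arrays in opposite directions, where 6.2 would be expected if the arrays were independent. Opposite genes thus exceeded that expectation by more than the same-way genes did. Of these, 129 were higher in Rbpj-cKO on replicate 1 and lower on replicate 2, and 18 the other way.

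Across genes, the log2 ratios of the arrays ran opposite ways (Pearson's r = -0.352, Spearman's rho = -0.473), and 30.8% of the genes had the same sign on both. Genes are not independent replicates, and no p is given. The SD across genes was 0.129 for the mean of both ratios and 0.185 for the deviation of an array from that mean.

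**Figure D2:**
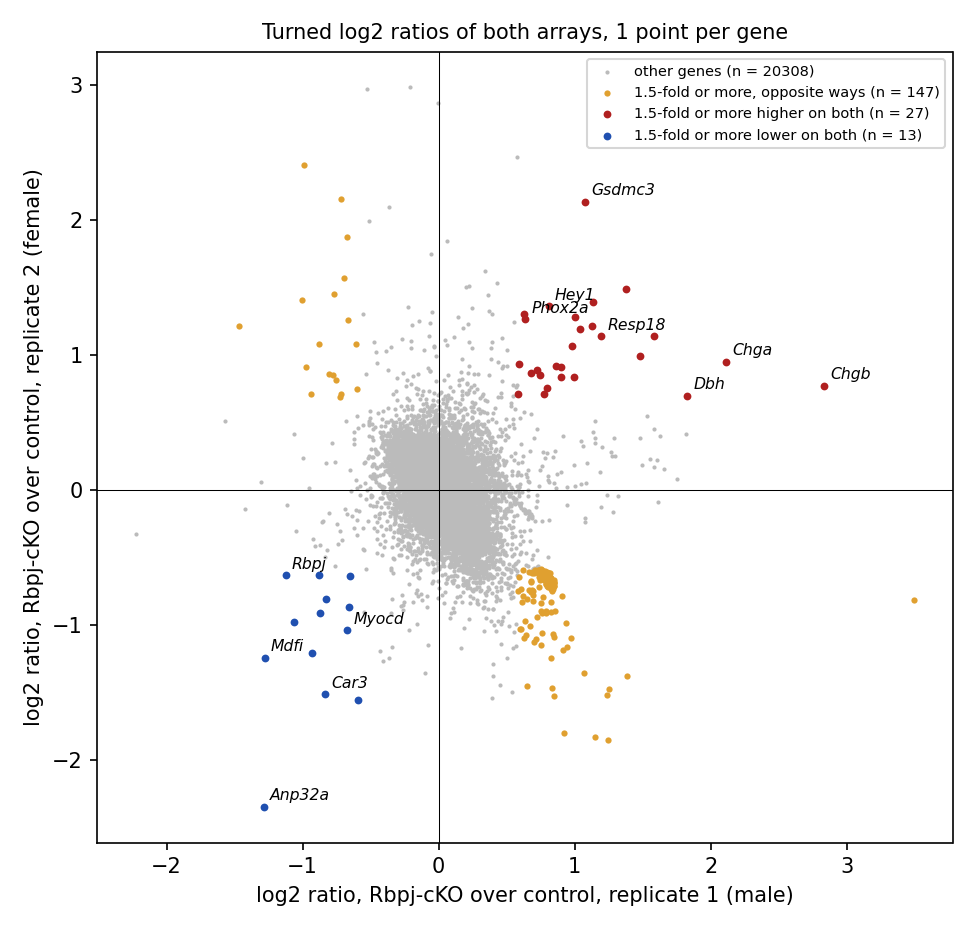
Log2 ratio of Rbpj-cKO over control on replicate 1 (male, horizontal axis) against replicate 2 (female, vertical axis), 1 point per gene, for 20495 genes. Red and blue points are the 27 genes higher and 13 genes lower by at least 1.5-fold on both arrays, and yellow points are the 147 genes with such differences in opposite directions. Most yellow points lie at the lower right.

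The Notch target list held 14 measured genes, of which 4 were higher and 1 lower on both arrays. Hey1 had 0.81 and 1.36, and Hey2 had 0.86 and 0.92, and these were the list members that passed when adjusted over the list alone (adjusted p = 0.0033 for each), against 0 over all genes. Hes1 had -0.24 and 0.48, Hes5 -0.06 and 1.24, Heyl -0.47 and 0.11, and Nrarp 0.08 and -0.25. As a list the targets were called higher by camera (adjusted p = 0.00383, median log2 ratio 0.042). However, the median was -0.0056 on replicate 1 and 0.12 on replicate 2, above 52.55% and 95.67% of random lists of like intensity. Both shares lay inside the central 95% of such lists. The list's mean was 0.187, with Hey1 (mean 1.08), Hey2 (0.89) and Hes5 (0.59) highest and Notch3 next at 0.18. The call therefore leans on few members and does not show a shift of the targets as a whole. The adjusted p was 0.755 with an estimated correlation, here and below a test that did not call the simulated shifted list either. Of the 29 receptors, ligands and cofactors, 5 were higher and 2 lower on both arrays, with a list median of 0.0048 (camera adjusted p = 0.432). Rbpj was the member of that list that passed when adjusted over the list alone (adjusted p = 0.0351). The ligand gene Jag1 had 0.29 and 0.45, Notch1 0.36 and 0.18, and Notch3 0.26 and 0.10.

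Among 16 smooth muscle regulators, 2 were higher and 3 lower on both arrays, and Myocd passed when adjusted over the list alone (adjusted p = 0.0138; adjusted p = 0.651 over all genes). The list as a whole had a median of -0.018 (camera adjusted p = 0.158). The 34 contractile and cytoskeletal genes had a median of -0.026 (camera adjusted p = 0.788), 0.11 on replicate 1 and -0.20 on replicate 2. Of these, 6 were higher and 4 lower on both arrays, and 24 had opposite signs. Acta2, smooth muscle actin, had 0.52 and -0.77, Myh11, smooth muscle myosin heavy chain, 0.04 and -0.14, Tagln 0.24 and 0.10, and Cnn1, calponin, -0.29 and -0.31. Pcp4, a calmodulin-binding peptide gene, had 0.77 and 0.71 and passed when adjusted over the list alone (adjusted p = 0.0313).

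The list of neural crest, glia and neuron genes had the lowest p of the 25 lists with the dyes turned as labelled. Of its 21 measured genes, 16 were higher on both arrays and 0 were lower on both, and the median log2 ratio was 0.45 (camera adjusted p = 1.78e-30). The former p rests on the preset correlation of 0.01, where the estimated one was 0.15, and does not measure the spread between samples. The adjusted p was 0.755 with an estimated correlation, and the unadjusted p 0.0979 there was the lowest of the lists. The medians were 0.14 on replicate 1 and 0.70 on replicate 2, above 99.6% and 100% of random lists of like intensity. When adjusted over the list alone, 7 members passed, among them Phox2a, Fabp7, Dbh, Chga and Chgb, against 0 over all genes. The arrays differed in which members stood highest. Th, the first enzyme of catecholamine synthesis, had 1.55 and 0.23, and Chgb 2.83 and 0.77. The neurofilament gene Nefl had -0.56 and 1.30. The glial genes Sox10 and Fabp7 had 0.20 and 0.38, and 0.63 and 0.58. Th, Nefl and Sox10 were chosen after their values were seen.

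Markers of other cell types moved with the arrays. Of 17 macrophage and leukocyte genes, 9 were higher and 0 lower on both arrays, with medians of 0.42 on replicate 1 and 0.0030 on replicate 2 (camera adjusted p = 5.93e-09). Cx3cr1 had 0.65 and 0.06 (means of 0.38 and 0.09 by its other probes), and Adgre1 0.49 and 0.21 (a mean of 0.23 by its other probe). Of 7 mesothelial genes, 3 were higher on both, with medians of 0.54 and 0.07 (camera adjusted p = 0.00111). Bnc1 had 0.81 and 0.07. The 14 erythroid genes had medians of 0.57 and -0.77 (camera adjusted p = 0.00327), and the 13 skeletal muscle genes 0.63 and -0.94 (camera adjusted p = 0.0184). In each of these lists 7 genes were at least 1.5-fold different in opposite directions. Myog, a myogenic transcription factor, had 0.22 and -0.96. All of these lists had an adjusted p of 0.755 with an estimated correlation. That correlation was 1 for macrophage, 0.429 for mesothelial, 0.714 for erythroid and 1 for skeletal muscle genes, against the preset 0.01.

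Urothelial and matrix genes were called lower by camera with the preset correlation. Of 28 urothelial genes, 10 were lower and 4 higher on both arrays, with a median of -0.026 (camera adjusted p = 0.00887). The tight junction gene Cldn4 had -0.53 and -0.58 (a mean of -0.54 by its other probe), and the basal keratin gene Krt5 -0.36 and -1.25. Of 30 fibroblast and extracellular matrix genes, 6 were lower and 2 higher on both arrays, with medians of 0.13 on replicate 1 and -0.28 on replicate 2 (camera adjusted p = 0.00887). Dpt, dermatopontin, had -0.35 and -0.80, and Pdgfra -0.20 and -0.55. For both lists the adjusted p was 0.755 with an estimated correlation.

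Apart from the Notch targets, lists of signalling pathways did not pass camera. The 17 genes of the retinoic acid pathway had a median of -0.067, with 4 higher and 6 lower on both arrays. Within it, Cyp26a1, which degrades retinoic acid, had -0.65 and -0.64 and passed when adjusted over the list alone (adjusted p = 0.0331), and Aldh1a3, which makes it, had 0.39 and 1.05. Of the 19 Wnt response genes, 6 were higher and 5 lower on both arrays. Wif1, a secreted Wnt inhibitor, had -0.55 and -0.91 and passed when adjusted over the list alone (adjusted p = 0.0378), and Axin2 had 0.04 and 0.13. The Wnt median of 0.027 was above 0 while its mean of -0.0059 and its test direction were below. The 13 Hedgehog response genes had a median of -0.012 (Ptch1 -0.06 and 0.05), and the 21 BMP and TGF-beta genes -0.021 (Bmp4 0.27 and 0.06). Immediate early and heat shock genes had a median of 0.0028, with 7 of 20 higher and 0 lower on both arrays, and Fos at 0.57 and 2.46. Proliferation genes had a median of -0.018 over 27 genes and p53 targets 0.029 over 16.

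Among the remaining lists, the 20 transcription factors of the ureteric mesenchyme had a median of -0.084 (camera adjusted p = 0.0534), with 7 lower and 3 higher on both arrays. Tbx2 had 0.17 and 0.52, and Twist1 -0.22 and -0.34. The 8 renal stroma genes had -0.15 (adjusted p = 0.0813), with Ntn1 at -0.35 and -0.58 (a mean of -0.15 by its other probe). Medians were 0.013 for endothelium, 0.023 for pericytes and vascular smooth muscle, 0.021 for nephron genes, 0.073 for ureteric bud and collecting duct, and -0.033 for gonad and adrenal. The nephron list's mean of -0.0070 was below 0 while its test direction was above. Over the 25 lists, camera called 8 at adjusted p under 0.05 with the preset correlation, 4 higher and 4 lower. With an estimated correlation it called 0, with 0 at an unadjusted p under 0.05, and fry called 0, with 2 at an unadjusted p under 0.05. On simulated spots neither called the list shifted by 0.4 (log2), with adjusted p = 0.89 for the estimated correlation and 0.536 for fry. With 2 arrays, their missing calls therefore do not show that no list shifted. Of 456 list entries, 14 passed when adjusted over the list alone, against 0 over all genes.

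**Figure D3:**
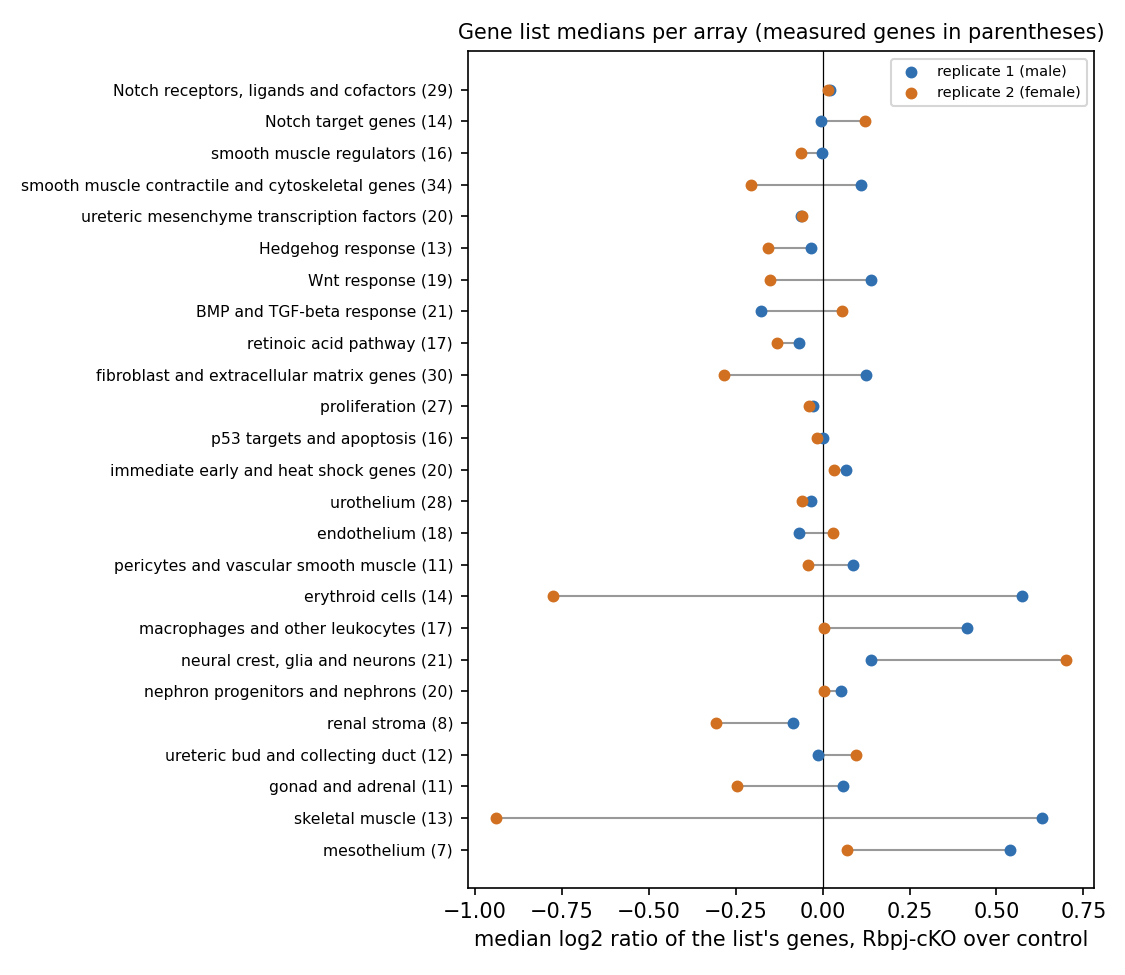
Median log2 ratio of Rbpj-cKO over control (horizontal axis) of each of the 25 tested gene lists, 1 row per list with its number of measured genes. Blue points are replicate 1 (male) and orange points replicate 2 (female). The neural list lies at 0.14 and 0.70, while erythroid (0.57 and -0.77) and skeletal muscle genes (0.63 and -0.94) lie on opposite sides of 0.

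The Y-linked genes Ddx3y and Eif2s3y had processed signals of 1530 and 2400 in male Rbpj-cKO, and of 1780 and 2400 in male control. In female control they were at 2.12 and 11.6, well above background on 0 and 2 of 4 spots. In female Rbpj-cKO they were at 123 and 214, well above background on 4 of 4 spots each, which is 8.04% and 8.94% of the male Rbpj-cKO signal. The X-linked transcript Xist, made from the inactive X chromosome, was well above background in both female channels and in neither male channel.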

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

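All tests weighed here were chosen after the results were seen, but the outcome had not been seen for those on base composition and on blood and muscle genes outside the fixed lists. With 1 array per sex, the differences between the male and the female pair were not tested.

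Among the genes, 147 differed at least 1.5-fold on both arrays in opposite directions. Lists fixed in advance stood apart in opposite directions as well, each outside the central 95% of random lists of like intensity on both arrays. The median log2 ratio of the male pair minus that of the female pair was 1.57 for skeletal muscle genes and 1.35 for erythroid genes. It was 0.409 for fibroblast and matrix genes, 0.315 for smooth muscle contractile and cytoskeletal genes and 0.29 for Wnt response genes. In the smooth muscle list, Tnnt2 (0.75 and -1.15) and Ldb3 (0.70 and -1.13), chosen after their values were seen, lay widest apart. Of its 34 genes 24 had opposite signs, while 6 were higher and 4 lower on both arrays. Whether this list went with the skeletal muscle genes was not tested. Among the named genes Chrna1, a muscle acetylcholine receptor subunit, differed at least 1.5-fold in opposite directions, with 0.65 and -1.45 and a difference of 2.10.

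A wrong dye orientation of 1 array in the labels was argued against by Rbpj, the targeted gene, but is not excluded. It would give Rbpj opposite signs in the male and the female pair. Both Rbpj probes were lower on both turned arrays, at -1.13 and -0.63, and at -0.48 and -0.37, with spot SDs of at most 0.115. The ratio nearest to 0 was only -1.48 SDs across the genes of its array, short of the bound set for exclusion. Where the probes lie relative to the deleted exons is not known. Dye bias of single probes may account for part of the opposite ratios. The base composition of the probes explained 17.9% of an array's deviation from the mean of both in 10-fold cross-validation, against 2.49% of that mean. Blood and muscle content that differed between the paired samples may account for another part, since genes of these cells outside the fixed lists stood apart the same way. The median deviation of replicate 1 from the mean of both was 0.225 for 11 erythroid genes and 0.505 for 10 skeletal muscle genes, higher than in at least 99.9% of 10000 random lists of like intensity. Without every gene of the fixed lists the correlation was still -0.369, so these lists are not the whole of the pattern. They hold only 439 of the 20495 genes, and other blood and muscle genes stay in. This value therefore does not tell how much of the pattern blood and muscle content explains. Sex stays open as untested.

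The Y-linked genes Ddx3y and Eif2s3y were at processed signals of 123 and 214 in the Rbpj-cKO channel of the female array, where the control channel held 2.12 and 11.6. A leak from the neighbouring male sub-array was argued against, because the control channel held at most 5.42% of the Rbpj-cKO channel's signal, while on the male array it held 116% and 100%. RNA of male embryos in the female Rbpj-cKO sample may be the source, since both genes were at a similar share of the male Rbpj-cKO level, with a ratio of 1.11 between the shares. These shares compare signals across arrays and dyes. The male control, in the same dye as female Rbpj-cKO, was at 1780 for Ddx3y and 2400 for Eif2s3y, so the ratio of 1.11 holds only for the comparison with male Rbpj-cKO. The other Y-linked probes, 1 of Kdm5d and 2 of Uty, were above background on 0 of 4 spots each in that channel, at processed signals of 2.15, 4.12 and 2.18. These exclude nothing, since their male Rbpj-cKO signals were only 13.8, 65.5 and 46.5, so such a share of them would be small. For Kdm5d it would lie below the floor of about 2.1 seen in female control. The brighter Uty probe was at 4.12 against 2.09 in female control, and the dimmer at 2.18 against 2.12. Xist was 22.1% and 20.6% lower in that channel than in female control by its probes, more than the shares of 8.04% and 8.94% that Ddx3y and Eif2s3y give. With 1 pair, whether this gap exceeds chance was not tested. Whether such RNA entered at dissection, pooling or labelling was not tested.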

How the results depend on the processing

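The test on the deviation of an array from the mean of both, the neural list without the catecholamine and granin genes, and the numbers expected from independent arrays were chosen after seeing the data. The cause was not tested for any change below.

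With limma, 0 genes had an adjusted p under 0.05 in the main fit and under all alternatives except the scanner's processed signals (1 gene, Gm19410) and an intensity trend with robust moderation (5 genes). The 372 genes at unadjusted p under 0.05 were 172 with median centring and 501 with no filter. Of those 5 genes, the mean log2 ratio rose with the processed signals from 1.14 to 2.49 for Gm19410, from 0.90 to 1.92 for 9430037G07Rik and from 1.26 to 1.81 for D030062O11Rik. The 1.5-fold count of 40 was 88 with the processed signals, 85 with the authors' fold changes and 9 at 2-fold, against 4.56 expected from independent arrays, and 359 to 614 genes on single arrays. All 40 genes were among those counted with the processed signals and the authors' fold changes, and 32 with median centring. The opposite count of 147 was 225 with the processed signals and 391 with median centring, where r was -0.512.

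Of the 25 lists, camera called 8, against 0 with an estimated correlation and 0 with fry. The last 2 tests did not call the simulated shifted list either. They leave the medians as they are: 0.042 for Notch targets, -0.039 fibroblast, -0.026 urothelium, -0.15 erythroid, 0.19 macrophages, 0.45 neural, -0.17 skeletal muscle and 0.34 mesothelium. The skeletal muscle call ended with scaling between arrays (-0.11) and with no filter (-0.14). On single arrays the medians were -0.0056 to 0.12 for Notch targets, -0.28 to 0.13 fibroblast, -0.77 to 0.57 erythroid, -0.94 to 0.63 skeletal muscle and -0.060 to -0.034 urothelium. The neural list was called under each processing alternative run with camera's preset correlation on the mean of both arrays, with adjusted p from 8.41e-57 to 4.08e-18. Without Th, Dbh, Chga and Chgb its median was 0.41 (camera adjusted p = 2.02e-19 with the preset correlation). The 5 members with opposite signs stayed in it, each lower on replicate 1 and higher on replicate 2, and the others were higher on both arrays. Tubb3, chosen after its value was seen, lay at that median with -0.06 and 0.88, so this result leans on replicate 2. Camera on the deviation of an array from the mean of both, which is the mean with 1 array turned the other way, called 6 lists, erythroid (adjusted p = 6.54e-07) and skeletal muscle (6.61e-07) lowest, and did not call the neural list (adjusted p = 0.134).

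Lists that were not called turned their test direction for Wnt response (medians 0.034 with processed signals, 0.027 with scaling and 0.027 with no filter), nephron genes (0.026 with processed signals, 0.011 with median centring) and endothelium (0.016 at offset 16, 0.0051 with median centring, 0.019 with scaling, 0.024 with the authors' values, 0.012 with the mean of probes). Ptch1 turned to 0.022 with the authors' values and 0.00054 with outlier spots kept, and Ccnb1 to -0.020 with the mean of probes. Lists called only elsewhere were immediate early genes and pericytes with median centring, ureteric mesenchyme factors with no filter and the mean of probes, and renal stroma with no filter.

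The fit with channels analysed separately was not run to an end, because the intraspot correlation reached its bound. Leaving out an array leaves no residual degree of freedom, so no test was made there. No paired analysis was possible beyond the main test, because that test already takes Rbpj-cKO over control within each array. Between 67.7% and 70.1% of the spots of a channel were well above background, which limits what dim genes can show.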

Other observations

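All tests in this part were chosen after the results were seen, but the outcome had not been seen for the one on further genes near the engineered loci.

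Among the named higher genes, some known from neuroendocrine cells lie outside the fixed lists, and their grouping was made after their values were seen. Slc18a1 had log2 ratios of 1.48 and 0.99, Resp18 1.19 and 1.14, Insm1 1.04 and 1.19, and Dusp26 0.98 and 1.07. Ren2 was higher on both arrays at 1.38 and 1.49, and Ren1, the other renin gene, had 1.0 and 0.19. The receptor gene Ret, which autonomic neurons and the ureteric bud both use, had -0.51 and 1.99.

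The higher neural genes were weighed against the dissection and the dyes. Dye bias of single probes as the whole cause was argued against. It would turn a gene's sign between the arrays as labelled, whereas 16 of the 21 genes were higher on both and 0 lower on both. Over all genes 30.8% had the same sign. The list's median lay above at least 99.6% of random lists on both arrays, but this adds little. Random lists hold genes drawn independently. On replicate 1 the Wnt response list, whose medians had opposite signs on the arrays, lay above 99.74% of them. Adrenal gland carried along as a whole was argued against too. The mean log2 ratio of Star, Cyp11a1, Cyp17a1, Hsd3b1 and Nr5a1 was 0.11 on replicate 1 and -0.17 on replicate 2. For Th, Dbh, Chga and Chgb the means were 2.08 and 0.663. The 95% intervals of the former, -0.092 to 0.312 and -0.305 to -0.035, were taken over the 5 genes. They hold the spread between genes on 1 array, not that between samples. Whether the same nerve tissue came with both samples stays open. Spearman's rho of the arrays over the 21 genes was -0.0727 (95% bootstrap interval -0.517 to 0.414), which decides nothing, because the arrays ran opposite ways over all genes too (rho = -0.473). What may remain is nerve or chromaffin tissue carried along with the Rbpj-cKO samples, of like or differing makeup, or a change in the ureter's own neural cells, which the data do not separate. All 21 genes were well above background in the control channel of at least 1 array as well, with Chgb at a log2 level of 12.8 on replicate 1.

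Several genes with large ratios lie near the engineered loci. Of 38 genes with coordinates that differed at least 1.5-fold the same way, Rbpj left out, 5 lie within 30 Mb of the Rbpj or Tbx18 probe on mm9, where 1.68 would be expected. The nearness was seen before it was counted, so no p is given. Ren2 has no coordinate in the files, so it was not placed or counted here. Pi4k2b at chromosome 5, position 53159457, had -1.07 and -0.98, and D030062O11Rik at chromosome 9, position 87626691, close to Tbx18, had 1.14 and 1.39. The others were 9430037G07Rik at position 88490190 with 0.90 and 0.91, Scg3 at 75491320 with 0.59 and 0.93, and Anp32a at 62225436 with -1.29 and -2.34, all on chromosome 9. The other 889 genes in these windows had a mean absolute log2 ratio of 0.0842, against a median of 0.0751 over random pairs of such windows (96.6th percentile), inside the central 95%, so a linked segment was neither supported nor excluded. A hypothesis is that some of these ratios may come from chromosome segments inherited with the engineered alleles, or from the Tbx18-Cre allele itself, rather than from the loss of Rbpj. The second probe of Anp32a, at a mean of 0.02, would go with a sequence variant under the first, and no sequence of the alleles was analysed here.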
